A study of Mus musculus with 6 samples.

How the data were processed

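Polyadenylated transcripts were measured by RNA sequencing in 6 libraries from C57BL/6 mouse bone marrow cells, which the labels call bone marrow derived macrophages. The cells came from wild-type (WT) mice or mice labelled as Otud1 knock-outs (Otud1 KO), aged 10 weeks, and had grown for 7 days with 20 ng/mL GM-CSF, a growth factor that also yields cells with dendritic features. Each genotype gave 1 mock library (0 h), 1 library after 6 h with HSV-1 (herpes simplex virus, strain 17) and 1 after 6 h with SeV (Sendai virus, Cantell strain). Each of the 6 groups therefore held 1 library, and the labels do not say whether libraries came from separate cultures or animals. By these labels every comparison of a virus with mock also spans 6 h, so virus and time cannot be told apart there. HSV-1 and SeV were both taken at 6 h.

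Per the labels, reads were called with CASAVA 1.8 and aligned with HISAT2 to the mouse genome GRCm38 (mm10). The read counter, the annotation release, any filter on genes and the method behind the scaling are not given in the sources used here. The deposited values are a gene-level signal: read counts divided by 1 size factor per library. They were turned back into whole reads by dividing by the value of 1 read in that library. All 18198 values of every library came within 0.001 reads of a whole number. Of the gene identifiers, 15958 matched GENCODE mouse release M21 with their version and 18156 without it, and 42 were not matched. Recovered totals ran from 21492940 to 29603631 reads per library. Intervals and floors cover counting error only, since duplicate reads cannot be told from independent molecules.

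Before the data were examined, tests were planned for 2 kinds of file, counts and normalised expression values. The plan for counts was the edgeR quasi-likelihood test, and that for normalised values was limma on log2 of the deposited values plus 0.5. The files held values between the 2 kinds. The main fit was limma 3.58.1 (R 4.3.3, no trend) on log2 of TMM-scaled CPM (the usual unit of reads relative to library size, with factors from edgeR 4.0.16) plus 0.5. It took the recovered reads, so it departs from both plans. Genes needed 1 CPM or more in at least 2 of the 6 libraries, which left 12128. The additive model had terms for infection and genotype, 4 coefficients and 2 residual degrees of freedom, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. In this model the WT library and the library labelled Otud1 KO of an infection state act as 2 samples of that state, the 3 states act as 3 samples of each genotype, and a response that differs between genotypes counts as error. Its p-values measure only the spread between these libraries. Values after ± are standard errors of this fit. A contrast of HSV-1 with SeV from the same fit was added after the data were seen.

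The 7 comparisons of single libraries have no test. A gene counted as different at 2-fold or more on the same log2 scale. Ratios carry a 95% Clopper-Pearson interval of the 2 read counts, single counts a Poisson interval, and a gene with 0 reads a floor of 3 reads per library. Responses were compared across genes by Pearson's r and Spearman's rho between comparisons that share no library, with no p-value because genes are not independent replicates.

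A total of 38 gene lists (pathways, cell types and sample quality) was fixed before the data were examined, and 33 had at least 3 genes passing the filter. For each list the calls were counted over all genes and adjusted over the list alone. In the comparisons of single libraries the median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 10 groups. Genes were named by a rule also fixed beforehand: per virus the 12 highest and 8 lowest with the same sign in both genotypes, ranked by the smaller change. Between genotypes the rule took the 10 highest and 10 lowest with the same sign in 3 states and the 5 highest and 5 lowest of each state. It also took up to 2 members at each end of every list and 13 genes named in all cases, and passed over 9 predicted or unnamed genes. A few genes outside the rule are named as chosen after their values were seen.

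The alternatives fixed beforehand were total-count scaling and median-of-ratios scaling, pseudocounts of 0.1 and 5, no filter and a filter at 5 CPM for the single-library comparisons. For the fits they were median-of-ratios scaling, no filter, limma with a trend, limma-voom, DESeq2 1.42.0 and leaving out each library in turn. Total-count scaling and both pseudocounts were added to the fits, and all alternatives to the list counts, after the data were seen. The edgeR quasi-likelihood test (genes with at least 10 reads in at least 2 libraries) was the plan for counts. Its use as an alternative to limma was decided after the data were seen. On simulated data of this design (dispersion 0.005, 200 changed genes per comparison), limma recovered 98.5% of genes with a 2-fold change between genotypes and made 11 false calls among 11659 genes. The simulation gave every gene the same dispersion and no response that differed between genotypes. Its share recovered therefore does not carry over to these data, where several genes with fitted differences above 2-fold did not pass. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest. Reads from the viral genomes were not analysed here.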

Results

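The series covers 6 mRNA-seq libraries of mouse bone marrow derived macrophages, 1 for each combination of genotype (WT or labelled Otud1 KO) and infection state (mock, HSV-1 for 6 h, SeV for 6 h). WT libraries held 22155038 reads (mock), 27377081 reads (HSV-1) and 29363481 reads (SeV), and those labelled Otud1 KO held 29603631, 21492940 and 25191902 reads. The 10 most abundant genes took 17.4% and 17.2% of reads in the mock libraries and 11.5% to 11.9% in the infected ones. Log expression across genes correlated at r = 0.995 to 0.996 between genotypes within a state, 0.848 to 0.873 between mock and infected libraries, and 0.930 to 0.932 between the viruses. No group had a replicate, so values of single libraries carry counting intervals only.

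Otud1 (ENSMUSG00000043415.5, chromosome 2, 19657752 to 19660583, GRCm38), a deubiquitinase and the gene the knock-out is named for, was read in every library. In WT cells it stood at 9.94 CPM in mock (277 reads; interval 8.80 to 11.2), 124.6 CPM with HSV-1 (120.0 to 129.3) and 184.8 CPM with SeV (179.9 to 189.9). In the libraries labelled Otud1 KO it stood at 23.1 CPM (854 reads; 21.6 to 24.8), 118.3 CPM and 351.1 CPM. The level labelled Otud1 KO was 2.33 times WT in mock (2.03 to 2.68), 0.95 times with HSV-1 (0.897 to 1.01) and 1.90 times with SeV (1.84 to 1.97). Otud1 reads were thus not lower by label in mock or SeV, and no loss was detectable with HSV-1. Over both genotypes Otud1 rose with HSV-1 (log2 change 2.96 ± 0.30, limma adjusted p = 4.5e-04) and with SeV (4.02 ± 0.30, adjusted p = 2.0e-04), higher in 2 of 2 genotypes each time. Gene counts do not show whether these transcripts encode the intact protein.

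**Figure D1:**
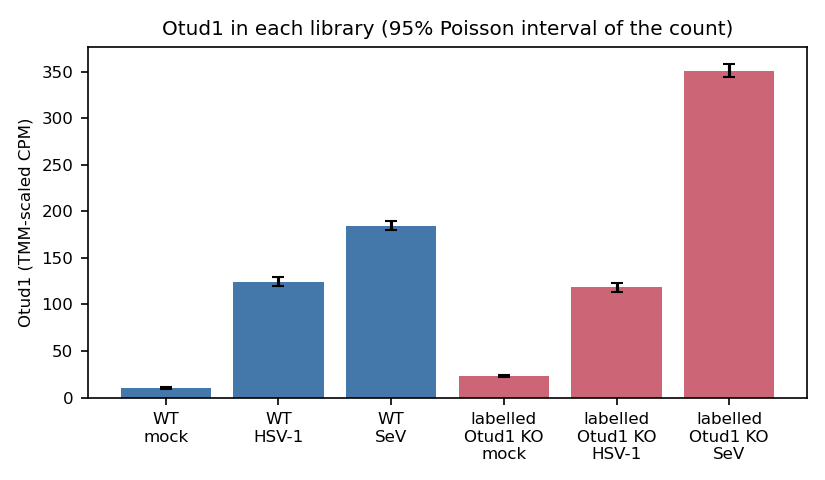
Otud1 in TMM-scaled CPM for each of the 6 libraries, with bars starting at 0 and 95% Poisson intervals of the count. The libraries labelled Otud1 KO stand at 23.1, 118.3 and 351.1 CPM in mock, HSV-1 and SeV, against 9.94, 124.6 and 184.8 CPM in WT.

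Mock and HSV-1 libraries were compared to find the transcripts that differed with this DNA virus in both genotypes. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981), which encodes the cytokine interleukin-6, rose from 0.251 to 861.5 CPM in WT and from 0.379 to 776.1 CPM in the libraries labelled Otud1 KO (log2 change 9.97 ± 0.14, adjusted p = 2.4e-06). Nos2, the inducible nitric oxide synthase, rose by 9.37 ± 0.17, the cytokine gene Il1a by 8.98 ± 0.14 and the chemokine gene Cxcl10 by 8.54 ± 0.09, to 5192 CPM in WT. Il27, Ptgs2 (the inducible cyclooxygenase), Cd69 (an activation marker), Tnfsf15, Edn1 (endothelin-1), Ifi205, Ccl4 and Cmpk2 rose by 8.63, 8.50, 8.50, 8.21, 7.87, 7.84, 7.83 and 7.62. The transcripts that fell furthest encode extracellular matrix proteins: Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) went from 205.6 to 0.357 CPM in WT and from 210.0 to 0.341 CPM by the other label (−7.94 ± 0.11, adjusted p = 2.4e-06). Col1a2 (−7.27 ± 0.10), Bgn (−6.71 ± 0.18), Sparc (−6.69 ± 0.12), Col5a2 (−6.08 ± 0.09) and Timp3 (−6.02 ± 0.10) fell as well, and Col12a1 went from 33.8 and 36.4 CPM to 0 reads in both HSV-1 libraries. For these matrix genes an effect of the virus cannot be told apart from stromal cells absent from, or lost in, the HSV-1 cultures (see the other observations). Cnr2, the cannabinoid receptor 2, fell by 5.64 ± 0.17. Each of these genes moved the same way in 2 of 2 genotypes, which the naming rule required, so this agreement is no separate evidence. Their adjusted p-values ran from 2.3e-06 to 8.5e-06 (limma).

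Most members of the antiviral and inflammatory lists rose with HSV-1, apart from the interferon genes themselves (6 of 15, list median 0.08); counts adjusted over the list alone were the same unless a second count is given. All 47 interferon-stimulated genes tested rose, from Lgals3bp (1.44 ± 0.09) and Irf9 (1.44 ± 0.09) to Mx1 (7.70 ± 0.17) and Ifi205 (7.84 ± 0.09); Isg15, Ifit1, Ifit2 and Irf7 rose by 5.72, 7.08, 7.25 and 5.15. The 6 interferon genes that rose (5 adjusted over the list alone) were led by Ifnb1 (5.55 ± 0.11) and Ifna2 (1.68 ± 0.09), while Ifna4 rose by 1.07 ± 0.18; the size of a fitted change from 0 reads in mock, as in Ifna2 and Ifna4, depends on the pseudocount. Of 12 early IRF3-responsive genes 11 rose, among them Rsad2 (7.60 ± 0.09), and Pmaip1 stood at −0.20 ± 0.15. All 17 guanylate-binding proteins and related GTPases rose, up to Gbp5 (7.19 ± 0.09) and Iigp1 (7.73 ± 0.22), as did all 19 inflammatory cytokines, with Tnf at 6.35 ± 0.15 and Il1b at 6.89 ± 0.11, and all 16 chemokines, with Ccl3 at 7.86 ± 0.15 and Ccl5 at 5.29 ± 0.10. Of 16 feedback genes of the NF-kB pathway 15 rose, including Tnfaip3 (4.12 ± 0.10) and Nfkbiz (5.15 ± 0.11). All 16 genes of MHC class I presentation rose, from H2-D1 (0.29 ± 0.10) to Nlrc5 (4.47 ± 0.10). The rise of H2-D1 is smaller than the shift of all genes under total-count scaling (−0.59), so its direction rests on the scaling. Of 24 nucleic acid sensors and adaptors 17 rose, among them Tlr3 (4.01 ± 0.11) and Nlrp3 (4.13 ± 0.09), and 3 fell, among them Tmem173, which encodes STING (−0.86 ± 0.09). Irf3 fell by 0.39 ± 0.09 (adjusted p = 0.011).

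Growth and metabolic lists moved in both directions. G2/M genes mostly fell (17 of 20, such as Aurkb, −2.06 ± 0.22), while 3 rose, including Mki67 (1.34 ± 0.10). Of 20 replication genes 12 fell, such as Mcm7 (−2.08 ± 0.12), and 4 rose (6 adjusted over the list alone), led by Ccne1 (3.06 ± 0.09). Cholesterol synthesis genes fell for 11 of 20, such as Dhcr7 (−2.59 ± 0.14), and rose for 6, though under total-count scaling 0 rose and 15 fell. Immediate early genes rose for 15 of 20, such as Egr1 (3.40 ± 0.10), and fell for 2, Egr2 (−1.75 ± 0.15) and Fos (−0.64 ± 0.12). Of 16 p53 targets 6 rose, led by Cdkn1a (3.65 ± 0.11), and 7 fell, led by Sesn1 (−3.58 ± 0.15). Of 20 lysosome and autophagy genes 5 rose, such as Sqstm1 (1.31 ± 0.10), and 6 fell, such as Tfeb (−2.97 ± 0.09); under total-count scaling 1 rose and 15 fell. Several lists changed direction with the scaling, and the next counts give total-count scaling second. NRF2 targets went from 7 up and 5 down of 19 (8 and 6 adjusted over the list alone), with Slc7a11 at 2.54 ± 0.09, to 4 and 12. The unfolded protein and ATF4 list went from 7 and 5 of 19, with Ppp1r15a at 2.77 ± 0.12, to 5 and 12, and heat shock genes from 8 and 3 of 12, with Hspa1b at 4.08 ± 0.15, to 4 and 4. Glycolysis and hypoxia genes went from 10 and 5 of 19, with Pfkfb3 at 2.61 ± 0.11, to 4 and 10. Oxidative phosphorylation genes went from 8 and 3 of 22 (7 and 3 adjusted over the list alone), with Cycs at 1.98 ± 0.10, to 1 and 16. Deubiquitinases of the ovarian tumor family and relatives went from 8 and 2 of 15 (7 and 2 adjusted over the list alone), with Usp18 at 5.93 ± 0.12, to 7 and 6. MHC class II genes rose for 3 of 9, such as H2-DMb1 (0.92 ± 0.10), against 2 up and 8 down of 10 under total-count scaling.

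Markers of other cell types moved with HSV-1 as well. Among 11 stromal and endothelial markers 7 fell (Col1a1, Col1a2, Col3a1, Dcn, Cxcl12, Sparc and Acta2) and 4 rose, including Pdgfrb (2.21 ± 0.13) and Kdr (1.71 ± 0.16). The 7 that fell kept a median of at most 0.403% of their mock level, and all except Cxcl12 (54.3%) kept under 2%; Col3a1 and Dcn had 0 reads in both HSV-1 libraries and were at least 248- and 107-fold lower (floor of 3 reads over the 2 libraries). With SeV the same 7 kept 80.2% to 112% of mock, median 87.6%. Of 15 macrophage markers 5 rose, such as Fcgr1 (3.36 ± 0.10), and 4 fell (3 adjusted over the list alone), such as Cx3cr1 (−3.14 ± 0.11); under total-count scaling 4 rose and 10 fell. Dendritic cell markers fell for 5 of 10, such as Clec9a (−3.22 ± 0.14), and rose for 2, among them Xcr1 (2.10 ± 0.15). All 3 plasmacytoid markers rose (Bst2 2.40 ± 0.12), as did 4 of 5 neutrophil markers (Lcn2 4.86 ± 0.11), 3 of 4 progenitor markers (Hoxa9 1.46 ± 0.22, while Cd34 fell by 1.88 ± 0.09; under total-count scaling 1 rose and 1 fell) and 2 of 3 T and NK markers (Lck 2.81 ± 0.15, Eomes 2.02 ± 0.09). Among genes linked to alternative activation 4 of 10 rose, such as Msr1 (1.92 ± 0.11), and 2 fell, led by Pparg (−2.73 ± 0.10), against 2 up and 4 down of 9 under total-count scaling.

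**Figure D2:**
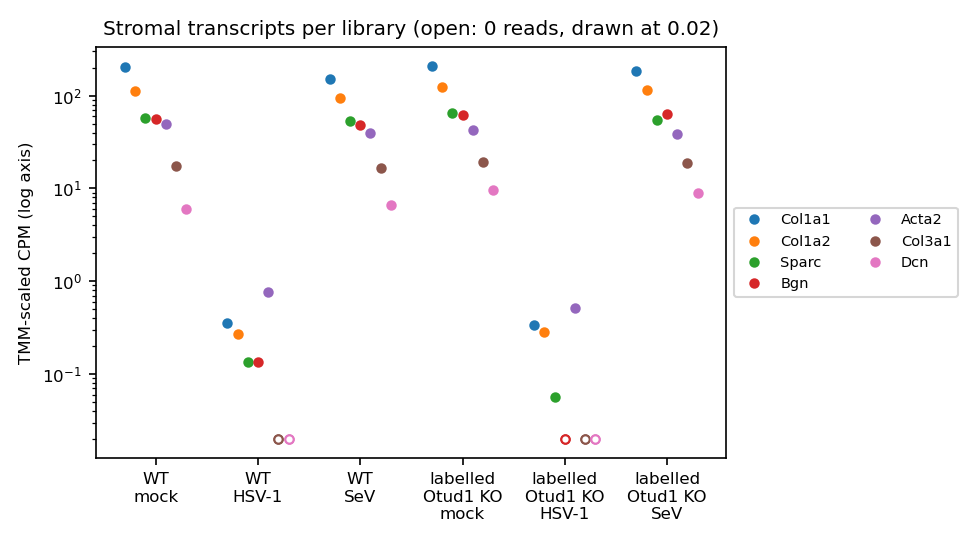
TMM-scaled CPM on a log axis of 7 stromal transcripts in each of the 6 libraries (a point is 1 library, open circles had 0 reads and are drawn at 0.02). Col1a1 lies between 152 and 210 CPM in mock and SeV libraries and at 0.357 and 0.341 CPM in the HSV-1 libraries.

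In limma 4212 genes rose and 4307 fell with HSV-1 at adjusted p under 0.05, of 12128 tested. Total-count scaling shifted the median of all genes by −0.59 and gave 2279 up and 7807 down of 12185, so the balance of directions rests on the scaling. By size alone 2089 genes were at least 2-fold higher and 1789 lower in WT, and 2055 and 1836 in the libraries labelled Otud1 KO; 1875 higher and 1491 lower were shared. Total-count scaling gave 1246 and 3863 in WT and 1268 and 3913 by the other label.

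SeV, an RNA virus, was compared with mock in the same way. Ifnb1 (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774), which encodes interferon beta, rose by 11.41 ± 0.11 (adjusted p = 2.4e-06). It went from 3 reads to 1680 CPM in WT, a ratio of 15600 with a counting interval of 5339 to 75660, and from 0 reads to 1337 CPM in the libraries labelled Otud1 KO, at least 16440-fold higher. Interferon alpha genes had 0 reads in both mock libraries and became abundant: in WT Ifna5 reached 440.5 CPM (at least 4093-fold higher) and Ifna2 346.6 CPM (at least 3220-fold), and Ifna4, Ifna6 and Ifna9 reached 232.9, 196.3 and 127.8 CPM. The cytokine genes Il27 and Il12b rose by 10.24 ± 0.21 and 8.97 ± 0.13, Il6 by 8.52 ± 0.14, Ccl4 by 8.44 ± 0.10, Ccl2 by 8.39 ± 0.18 and Il1a by 8.32 ± 0.14. The genes that fell furthest were Cnr2 (−5.29 ± 0.17), Tifab, an inhibitor of TRAF6 signalling (−4.76 ± 0.10), Galnt9 (−4.66 ± 0.20), Arhgap25 (−4.62 ± 0.13), Tsc22d3, the glucocorticoid-induced leucine zipper (−4.57 ± 0.22), Eepd1 (−4.46), Arhgap19 (−4.46) and Lhfpl2 (−4.19). Directions held in 2 of 2 genotypes for every gene named here, again as the naming rule required, with adjusted p-values from 2.4e-06 to 4.3e-05 (limma).

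Interferon and inflammatory lists rose with SeV too, again with the same counts adjusted over the list alone unless given. All 15 interferon genes rose, the least Ifna7 (2.05 ± 0.16), and all 47 interferon-stimulated genes, from Lgals3bp (0.77 ± 0.09) to Ifi205 (8.04 ± 0.09), with Isg15 at 6.83, Ifit1 at 7.18, Ifit2 at 6.57 and Irf7 at 3.73. Early IRF3-responsive genes rose for 11 of 12, with Pmaip1 at −0.04 ± 0.15, and Irf3 itself stood at −0.14 ± 0.09 (adjusted p = 0.21). The guanylate-binding list rose for 16 of 17 (Gbp5 7.15 ± 0.09), inflammatory cytokines for 19 of 19 (Tnf 5.93 ± 0.15, Il1b 5.04 ± 0.11), chemokines for 15 of 16 (Cxcl10 7.06 ± 0.09, Ccl5 6.00 ± 0.10) and MHC class I genes for 15 of 16 (Tap1 2.57 ± 0.09). NF-kB feedback genes rose for 14 of 16 (Tnfaip3 4.28 ± 0.10), while Tnip3, an inhibitor of this pathway, fell by 1.56 ± 0.09. Sensors rose for 15 of 24 (Tlr2 2.91 ± 0.10) and fell for 3, among them Tlr4 (−1.44 ± 0.10) and Mavs, the adaptor of RNA sensing (−0.57 ± 0.11).

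Growth and metabolic lists moved in both directions with SeV as well. Cholesterol synthesis genes fell for 15 of 20, such as Lss (−2.05 ± 0.11), and rose for 2, or 0 under total-count scaling, where 18 fell. NRF2 targets fell for 15 of 19, such as Hmox1 (−1.92 ± 0.09) and Osgin1 (−2.25 ± 0.10), and rose for 3. Glycolysis and hypoxia genes fell for 10 of 19 (11 adjusted over the list alone), such as Pfkl (−1.39 ± 0.10), and rose for 3, led by Pfkp (2.39 ± 0.09). G2/M genes fell for 13 of 20 (14 adjusted over the list alone), such as Cdc20 (−1.35 ± 0.10), though Bub1b rose by 3.05 ± 0.11 and Mki67 by 2.78 ± 0.10. Replication genes fell for 11 of 20 (Mcm2 −1.39 ± 0.10) and rose for 6 (Ccne1 3.36 ± 0.09). Of 16 p53 targets 4 rose (Mdm2 2.38 ± 0.10) and 8 fell (9 adjusted over the list alone; Sesn1 −3.13 ± 0.15). Lysosome and autophagy genes fell for 8 of 20 (Tfeb −2.66 ± 0.09) and rose for 3, or 0 under total-count scaling, where 17 fell. Immediate early genes rose for 9 of 20 (Egr1 4.26 ± 0.10, Klf4 3.79 ± 0.10) and fell for 7 (Egr2 −2.35 ± 0.15), with a median of 0.08 that became −0.15 under total-count scaling. Total-count scaling also turned the unfolded protein list from 10 up and 5 down of 19 (Ppp1r15a 5.16 ± 0.12) to 5 and 7, and oxidative phosphorylation from 7 and 1 of 22 (Cycs 1.09 ± 0.10) to 2 and 7. Heat shock genes rose for 6 of 12 (5 adjusted over the list alone; Dnaja1 1.47 ± 0.11), with 5 up and 2 down under total-count scaling, and deubiquitinases rose for 7 of 15 and fell for 3 (Otulin −0.72 ± 0.10), with 7 and 5 there.

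Among cell type markers, 8 of 15 macrophage genes fell with SeV, led by Cx3cr1 (−3.95 ± 0.11), and 3 rose, led by Mertk (2.44 ± 0.09). Dendritic cell markers split, with 4 of 10 up (Xcr1 3.62 ± 0.15, Zbtb46 2.87 ± 0.12) and 5 down (Clec9a −3.02 ± 0.14), as did genes of alternative activation, with 4 of 10 up (Msr1 1.21 ± 0.11) and 2 down (Pparg −2.77 ± 0.10), or 2 and 5 of 9 under total-count scaling. Plasmacytoid markers rose for 2 of 3 (Bst2 1.27 ± 0.12), neutrophil markers fell for 4 of 5 while S100a8 rose by 1.54 ± 0.09, and T and NK markers gave 1 up (Lck 2.95 ± 0.15) and 1 down (Cd4 −0.48 ± 0.16) of 3. Progenitor markers gave 1 up (Ly6a 1.10 ± 0.14) and 2 down (Cd34 −1.88 ± 0.09) of 4. Stromal and endothelial markers rose for 3 of 11 (Kdr 1.17 ± 0.16), against 2 up and 5 down under total-count scaling, and MHC class II genes rose for 2 of 9, among them the regulator Ciita (0.86 ± 0.12), against 1 up and 5 down of 10.

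limma called 3949 genes up and 3981 down with SeV, against 2545 and 6428 under total-count scaling, which shifted the median of all genes by −0.35. At least 2-fold, 1710 genes were higher and 1346 lower in WT, and 1711 and 1356 in the libraries labelled Otud1 KO. Of these, 1510 higher and 1070 lower were shared. Total-count scaling gave 1210 and 2455 in WT and 1249 and 2451 by the other label, so the balance of directions rests on the scaling here too.

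**Figure D3:**
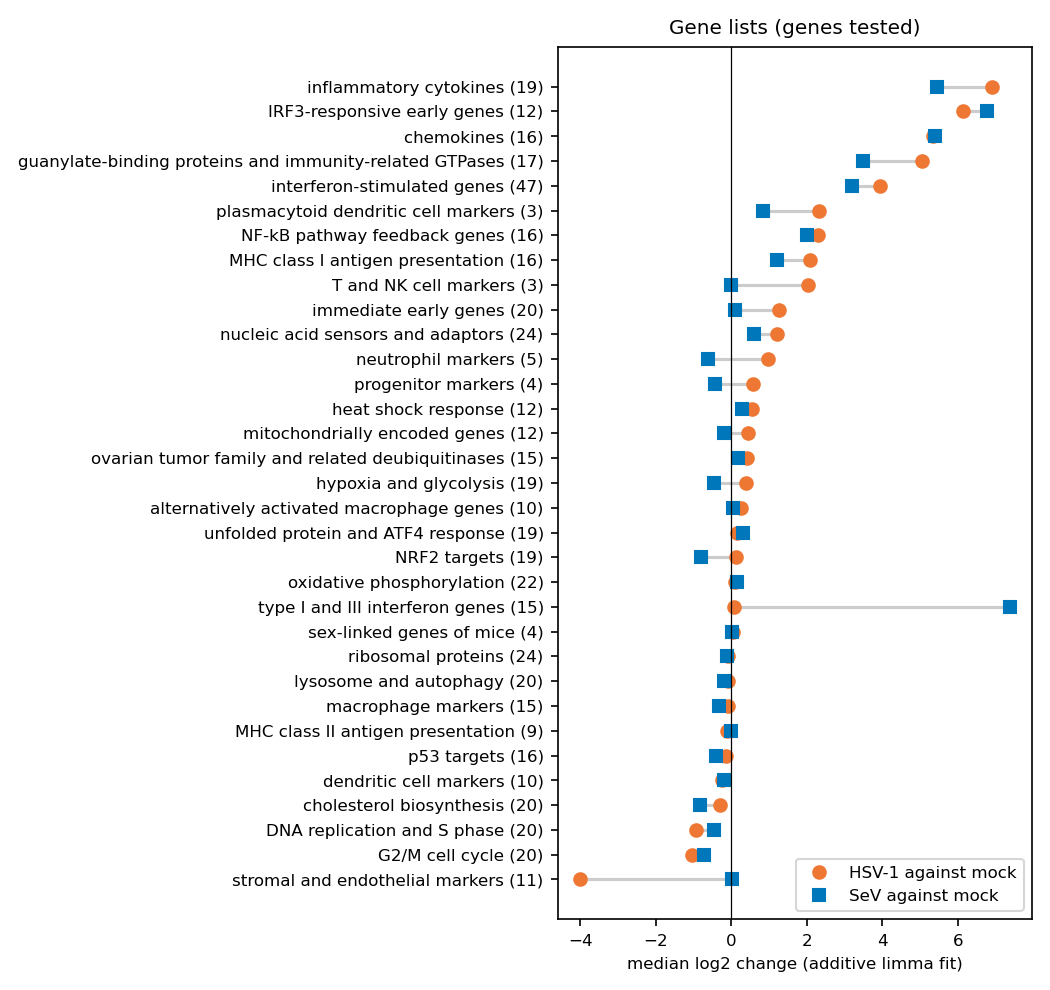
Median log2 change of the genes tested in each of 33 gene lists (number of genes in brackets) with HSV-1 (circles) and SeV (squares) against mock, from the additive limma fit with TMM scaling. Inflammatory cytokines lie at 6.89 and 5.45 and G2/M genes at −1.06 and −0.72, while interferon genes lie near 0 with HSV-1 and furthest right with SeV; medians of 9 lists with HSV-1 and 8 with SeV change sign under total-count scaling, including stromal markers with SeV, and that of MHC class II with SeV does so under median-of-ratios scaling.

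Contrasting the viruses directly, all 15 interferon genes were lower with HSV-1 than with SeV (Ifnb1 −5.86 ± 0.11, Ifna5 −8.70 ± 0.14), also adjusted over the list alone. Interferon-stimulated genes were higher with HSV-1 for 36 of 47, such as Mx1 (3.01 ± 0.17) and Usp18 (2.20 ± 0.12), and lower for 3, among them Isg15 (−1.10 ± 0.11). Higher with HSV-1 were also 14 of 17 guanylate-binding proteins and GTPases (Tgtp2 3.15 ± 0.20), 17 of 19 NRF2 targets (Hmox1 3.23 ± 0.09), 14 of 19 glycolysis and hypoxia genes (Egln3 2.16 ± 0.09) and 13 of 20 cholesterol genes (Hsd17b7 1.31 ± 0.10). Inflammatory cytokines split by gene: Nos2 was higher with HSV-1 (3.58 ± 0.17) and Il23a, a subunit of interleukin-23, was lower (−4.67 ± 0.18), with 11 up (12 adjusted over the list alone) and 6 down of 19. Chemokines gave 6 up (Cxcl3 4.29 ± 0.09) and 6 down (Ccl22 −5.16 ± 0.22). Stromal and endothelial markers were lower with HSV-1 for 7 of 11 and higher for 3, with a median of −4.03. The cultures may thus differ in cell makeup as well as in virus, and how far that bears on the other lists was not tested. Otud1 was lower with HSV-1 (−1.07 ± 0.30, adjusted p = 0.032). In all 2975 genes were higher and 2984 lower, or 2019 and 5279 under total-count scaling, whose shift here was −0.24.

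The libraries labelled Otud1 KO were compared with WT to see what differs by genotype, bearing in mind that Otud1 itself was not lower by label in mock or SeV and showed no detectable loss with HSV-1. Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221), a T cell co-receptor also found on some myeloid cells, was 4.98 times WT in mock (3.75 to 6.72), 6.40 times with HSV-1 (4.43 to 9.48) and 4.0 times with SeV (2.84 to 5.72), a log2 change of 2.04 ± 0.13 over the 3 states. Itgad (integrin alpha D, ENSMUSG00000070369.13, chromosome 7, 128154376 to 128223816) and Pla2g2d (a secreted phospholipase, ENSMUSG00000041202.12, chromosome 4, 138775735 to 138782046) were higher by 1.39 ± 0.09 and 1.16 ± 0.07. They stood at 1.55 and 1.19 CPM in the mock library labelled Otud1 KO. In WT mock, HSV-1 and SeV, Itgad stood at only 0.215, 0.179 and 0.21 CPM. Pla2g2d stood at 0.287, 0.223 and 0.384 CPM in the same libraries. These WT levels lie below the pseudocount, so both fitted changes and their standard errors depend on it. Chil3 (ENSMUSG00000040809.10, chromosome 3, 106147554 to 106167564), a chitinase-like marker of alternative activation, was lower at 4.26 against 14.4 CPM in mock (0.295 times, 0.244 to 0.356), and lower by −1.77 ± 0.09 overall. Gdf3 (ENSMUSG00000030117.5, chromosome 6, 122605403 to 122610087), of the TGF-beta family, differed by −1.45 ± 0.08. These 5 genes passed in limma (adjusted p = 0.031 for each, same direction in 3 of 3 states, as the naming rule required). Other genes ranked by the rule did not pass: Ptprm (1.17 ± 0.09, adjusted p = 0.071), Tpm3-rs7 (1.13), Slc45a3 (1.15), Mid1 (1.05), Itga9 (1.03), Fcna (0.94) and Spic (0.90) stood above 0, and Eps8l1 (−1.03), Pf4 (−0.99), Slc39a4 (−0.79), Slc24a5 (−0.79), Cxcl3 (−0.78), Pcbp3 (−0.69), Akr1b8 (−0.61) and Asrgl1 (−0.57) below. Fcna lies within 20 Mb of Otud1 on chromosome 2, as does Mrc1.

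**Figure D4:**
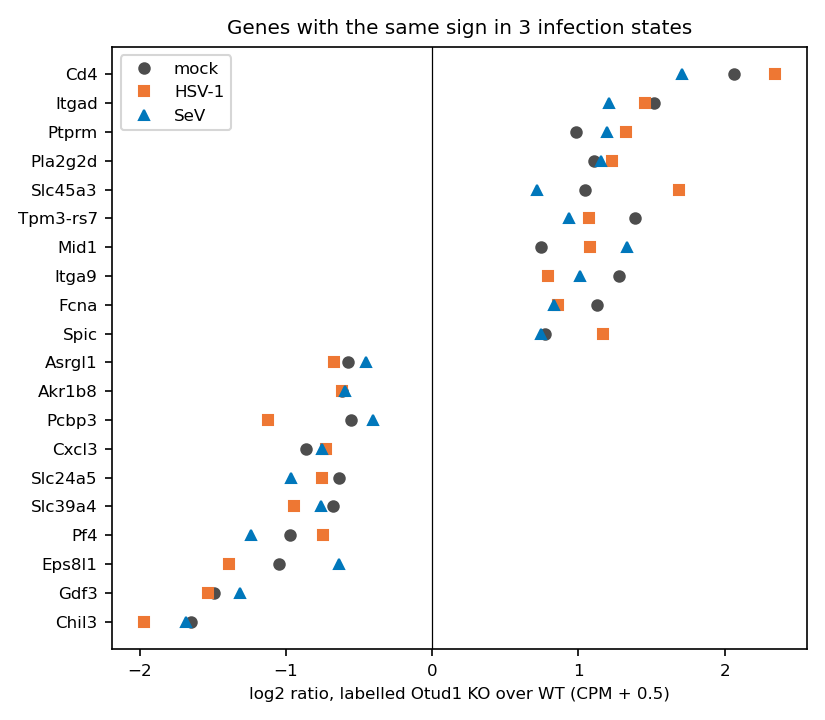
Log2 ratios of libraries labelled Otud1 KO over WT in mock (circles), HSV-1 (squares) and SeV (triangles) for the 10 highest and 10 lowest genes with the same sign in 3 states; each point is a ratio of 2 libraries. Cd4 lies highest, at up to 2.35, and Chil3 lowest, at down to −1.97.

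Antiviral genes differed little by label. Ifnb1 with SeV was 0.796 times WT in the library labelled Otud1 KO (0.785 to 0.807) and 0.998 times with HSV-1 (0.880 to 1.13), and its difference over 3 states was −0.20 ± 0.09 (limma adjusted p = 0.73). Isg15 with SeV was 0.871 times WT, and Il6 0.832 times. As lists, interferon genes with SeV lay above 0 by label for 12 of 15 (median 0.15, percentile 94.9 of random lists) and guanylate-binding genes for 14 of 17 (0.25, percentile 100). Guanylate-binding genes lay at 0 in mock and 0.07 with HSV-1 (percentiles 47.5 and 97.7), and early IRF3-responsive genes at 0.06, 0.07 and −0.03 in mock, HSV-1 and SeV (90.2, 98 and 20.5). Among the 13 genes named in all cases Otud1 differed most in limma (0.68 ± 0.24, adjusted p = 0.64), and of the 33 lists only those with Cd4 (T and NK markers) and Chil3 (alternative activation) had a member passing over all genes. Adjusted over the list alone, 4 MHC class II genes (such as H2-Eb1, 0.36 ± 0.08), 5 macrophage markers (such as C1qa, 0.48 ± 0.09), 5 G2/M genes (such as Bub1, 0.54 ± 0.08), 1 early IRF3-responsive gene (Oasl1, 0.56 ± 0.11), 2 genes of alternative activation (Mrc1 0.35 ± 0.08 and Ear2 0.72 ± 0.17) and Cd4 were higher, and 1 chemokine (Cxcl3), 1 cholesterol gene (Lss, −0.47 ± 0.09), 1 p53 target (Gdf15, −0.55 ± 0.10) and Chil3 were lower. In single libraries cholesterol synthesis genes lay below 0 for 19, 18 and 18 of 20 in mock, HSV-1 and SeV (medians −0.18, −0.18 and −0.22), lower than in all 10000 random lists each time. These percentiles, here and below, do not show a difference by genotype, since genes of a list may move together between any 2 cultures. Median ratios of MHC class II genes were 0.19, 0.20 and 0.18 (percentiles 99.9, 100 and 99.8) and of interferon-stimulated genes 0.13, 0.06 and 0.12 (100, 99.99 and 100). NRF2 targets lay at −0.03, −0.20 and −0.23 (percentiles 16.3, 0 and 0) and G2/M genes at 0.10, 0.31 and 0.29 (92.5, 100 and 100). Lists that reflect sample quality also moved between the same libraries: mitochondrially encoded genes lay at 0.48, −0.16 and 0.15 (percentiles 100, 0 and 99.9). Ribosomal protein genes lay at −0.22 with SeV, below 0 for 24 of 24 (percentile 0). The interval of the median held 0 for MHC class II and mitochondrial genes with SeV, for NRF2 targets in mock, and for G2/M genes in mock and SeV. It also held 0 for guanylate-binding genes in mock and with HSV-1, and for early IRF3-responsive genes in all 3 states.

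Single-library ratios singled out few genes: 18 at least 2-fold higher and 9 lower by label in mock, 31 and 32 with HSV-1, and 22 and 13 with SeV, of which 3 higher and 2 lower were shared by all 3 states. The numbers rest on the pseudocount. With 0.1 they were 79 and 54 in mock, 95 and 150 with HSV-1 and 97 and 63 with SeV. With 5 they were 4 and 3, 4 and 4, and 2 and 3. Genes ranked within single states included Vcam1 (1.57) and Igha (−1.27) in mock, Paqr9 (1.94), Epb41l3 (1.92) and Adam19 (−1.63) with HSV-1, and Eif3j2 (2.46), Slco2b1 (1.55), Slfn4 (1.25) and mt-Co2 (−1.55) with SeV. No difference between states was tested, and Slco2b1 also stood at 1.46 in mock and Slfn4 at 1.07 with HSV-1. The limma count of 3 higher and 2 lower (469 and 454 at unadjusted p under 0.05) depends on the tool. The edgeR test, planned for counts, gave 94 and 35, limma-voom 79 and 28, DESeq2 56 and 18 and limma with a trend 53 and 18. Leaving out any library in limma gave 0 and 0 (382 to 482 and 318 to 498 at unadjusted p under 0.05). Such a fit has 1 residual degree of freedom, against 2 in the main fit, so its 0 calls may only reflect lost power. Of the 5 limma genes, edgeR, voom, trend and median-of-ratios calls held 5, DESeq2 and total-count scaling 4, a pseudocount of 5 held 3, and a pseudocount of 0.1 or no filter 0. edgeR also called Otud1 higher by label.

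Whether the response to a virus differs by genotype was read from ratios of ratios, which have no test here. The fold change labelled Otud1 KO was at least 2-fold above that of WT for 42 genes and below it for 83 with HSV-1, and for 55 and 50 with SeV, whichever way the gene itself moved. These counts rest on the pseudocount: they rose with 0.1 and fell to a few genes with 5, as given under the processing. Otud1 was 12.5 times mock with HSV-1 in WT (11.1 to 14.2) and 5.11 times by the other label (4.72 to 5.54), and 18.6 and 15.2 times with SeV. Interferon-stimulated genes, higher by label in each state, had slightly smaller responses by the other label. Median log2 differences were −0.10 with HSV-1 (31 of 47 below 0, percentile 0.04) and −0.10 with SeV (28 of 47, percentile 0.24, interval holding 0). Both subtract the same mock ratio by label (median 0.13 for this list), so the 2 viruses are not separate observations. MHC class I genes went the other way with HSV-1 (0.13, 13 of 16 above 0, percentile 99.9). Across genes the responses of the genotypes correlated at r = 0.973 (rho 0.95) for HSV-1 and 0.967 (0.929) for SeV, and at 0.727 (0.721) and 0.718 (0.707) between viruses and genotypes. Ratios by genotype label correlated weakly between states, at 0.10 (0.068) for mock with HSV-1, 0.058 (0.012) for mock with SeV and 0.153 (0.119) for HSV-1 with SeV. Genes are not independent replicates, and 1 library per state cannot separate a genotype from its culture.

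**Figure D5:**
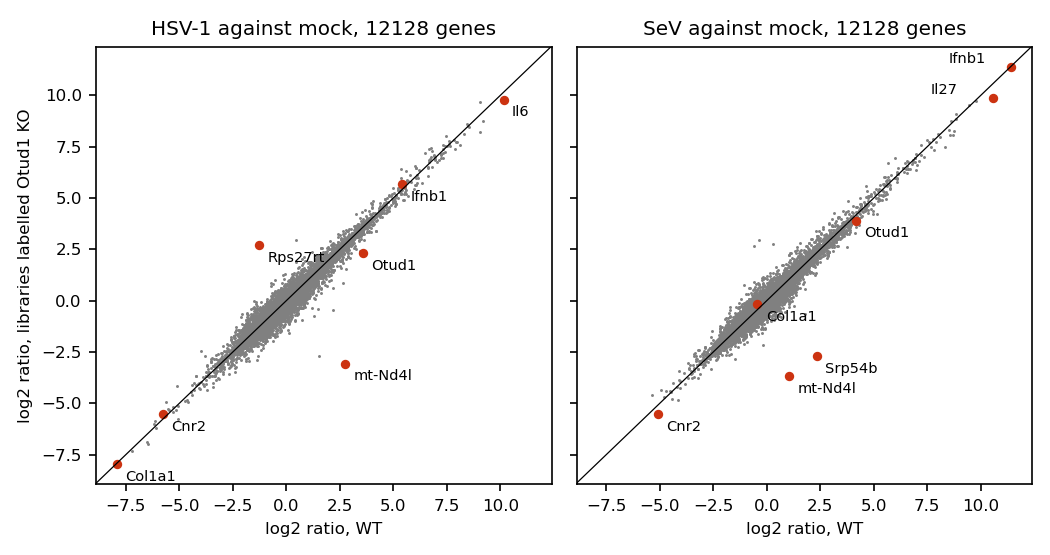
Log2 ratios to mock for 12128 genes in WT (x axis) against the libraries labelled Otud1 KO (y axis), for HSV-1 (left) and SeV (right), with the line of equal change; each grey point is a gene. Responses correlate at r = 0.973 and 0.967, while mt-Nd4l lies off the line at 2.76 in WT and −3.08 by the other label with HSV-1.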

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

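No test was run on the differences in this part, and the weighing of 3 other patterns under the other observations rests on tests all chosen after the results were seen. In 4 genes the single library of each genotype moved in opposite directions against its mock by at least 2-fold, and the difference between genotypes was not tested. Rps27rt moved by −1.26 with HSV-1 in WT and by 2.70 in the library labelled Otud1 KO, a difference of 3.96 on the log2 scale. Srp54b moved with SeV by 2.34 in WT and −2.72 by the other label, a difference of −5.06. For mt-Atp6 with HSV-1 the values were 1.54 and −2.70, a difference of −4.24. Another mitochondrial gene, mt-Nd4l, gave 2.76 and −3.08 with HSV-1, a difference of −5.84, and 1.05 and −3.68 with SeV, a difference of −4.73. Its level was 1.04 CPM in WT mock and 13.8 CPM in mock labelled Otud1 KO. Over the 3 states no difference by label passed in limma for Rps27rt (−0.33 ± 0.78), Srp54b (−0.89 ± 0.90), mt-Atp6 (−0.49 ± 0.85) or mt-Nd4l (−0.31 ± 1.10). Log2 ratios by label changed sign between mock, HSV-1 and SeV, at −1.735, 2.22 and −1.46 for Rps27rt and 1.68, −0.96 and −3.38 for Srp54b. For mt-Atp6 they were 0.96, −3.28 and 0.83, and for mt-Nd4l 3.21, −2.63 and −1.52. The read counter is not given, so it is unknown how reads matching more than 1 gene were assigned.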

How the results depend on the processing

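Total-count scaling and both pseudocounts for the fits, and all alternatives for the list counts, were chosen after the data were seen. So was the use of edgeR, the test planned for counts, as an alternative to limma. No paired analysis was possible by replicate number because each group has 1 library; the additive fit itself sets the genotypes against each other within each infection state. The lone library of a group is assumed to vary like the others where a library is left out. Median-of-ratios scaling kept each count of genes within 1.5 times its main value. The cause of the changes below was not tested, except that a stricter filter or none changes how many low-count genes are counted.

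Genotype counts moved most. Against 3 higher and 2 lower in limma, DESeq2 gave 56 and 18, edgeR 94 and 35, limma with a trend 53 and 18, limma-voom 79 and 28, and a pseudocount of 5 gave 31 and 13. No filter gave 0 and 0 (595 and 573 at unadjusted p under 0.05), a pseudocount of 0.1 gave 0 and 0 (429 and 395), and leaving out each library in limma ranged from 0 to 0 for higher and for lower (382 to 482 and 318 to 498 unadjusted). With a library left out only 1 residual degree of freedom remained, so these 0 calls may only reflect lost power. Without a library, HSV-1 counts ranged from 3403 to 4113 higher and from 3362 to 4330 lower, and SeV counts from 3046 to 3817 and from 2884 to 3961.

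Under total-count scaling limma gave 2279 higher and 7807 lower with HSV-1, 2545 and 6428 with SeV, and 5279 lower with HSV-1 than with SeV. Genes at least 2-fold numbered 1246 higher and 3863 lower for WT HSV-1, 1268 and 3913 for labelled Otud1 KO HSV-1, and 2455 and 2451 lower for SeV in WT and by the other label, and 21 were lower by label with HSV-1. Otud1 stood at 12.5 and 101.9 CPM in WT mock and HSV-1 and at 28.9, 96.9 and 342.8 CPM in mock, HSV-1 and SeV labelled Otud1 KO. Lists with most of their genes lower numbered 14 with HSV-1 and 14 with SeV, against 4 and 7. List medians reversed for MHC class II in WT SeV (−0.16) and for heat shock with SeV in WT (−0.0046) and by the other label (−0.10).

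With a filter at 5 CPM r was 0.983 between genotypes for HSV-1 and 0.980 for SeV, 0.749 and 0.739 between viruses, and 0.212 for ratios by label with HSV-1 and SeV. Responses differed at least 2-fold for 25 genes (HSV-1) and 22 (SeV). By label 8 genes were higher in mock, 7 higher and 9 lower with HSV-1 and 4 higher with SeV, and 1126 and 1162 were lower with HSV-1 in WT and by the other label. A pseudocount of 5 gave r of 0.984, 0.980, 0.763, 0.751 and 0.204, and 4 and 6 response differences. By label it gave 4 higher and 3 lower in mock, 4 and 4 with HSV-1 and 2 and 3 with SeV, and 644 and 585 genes lower in WT with HSV-1 and SeV and 627 and 541 by the other label.

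No filter gave 276 and 211 response differences, and by label 35 higher and 18 lower in mock, 48 and 56 with HSV-1 and 36 higher with SeV. A pseudocount of 0.1 gave 444 and 355, and by label 79 and 54, 95 and 150, and 97 and 63. For single named genes, values in the fits stayed on their side of the threshold in 1453 cases, passed it only under the alternative in 75 and lost it in 52; single-library ratios moved beyond counting error in 39 of their cases and stayed within it in 133. List medians stayed within their intervals in 1420 cases, moved beyond them in 62 and reversed in 3, where reversed means a change of sign with an interval that excluded 0; signs also changed in 67 of the other cases, whose intervals held 0, 33 of them under total-count scaling. Depth limits ratios that involve a level well below 1 CPM, where a few reads decide the value.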

Other observations

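Tests of explanations in this part were all chosen after the results were seen. Transcripts of sample quality and of rarer cell types, fixed as lists beforehand, complete the picture (limma; ± is the standard error). Of 12 mitochondrially encoded genes 4 rose with HSV-1 (2 adjusted over the list alone), led by the ribosomal RNAs mt-Rnr2 (1.22 ± 0.13) and mt-Rnr1 (1.10 ± 0.13), against 2 up and 1 down under total-count scaling, and 2 rose with SeV (0 adjusted over the list alone), against 0 up and 7 down. Mitochondrial genes took 3.59% of reads in WT mock and 4.8% in mock labelled Otud1 KO. Ribosomal protein genes fell for 1 of 24 with HSV-1 (Rpl10a, −0.42 ± 0.10) and 2 with SeV (Rpl10a, −0.35 ± 0.10, and Rpl3, −0.33 ± 0.10), 0 adjusted over the list alone, but total-count scaling gave 24 and 23 down. Y-linked genes were read in all libraries; of 4, Eif2s3y (0.31 ± 0.09) and Ddx3y (0.42 ± 0.13) rose with HSV-1 and Kdm5d fell by 0.57 ± 0.11, against 0 up and 3 down under total-count scaling. With SeV, Eif2s3y rose and Kdm5d and Uty fell (2 up and 2 down adjusted over the list alone), against 0 up and 2 down.

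Of 5 lists with too few genes for a count, 2 of 10 histone genes in the data were tested: Hist1h3d rose with HSV-1 (1.11 ± 0.12) and fell with SeV (−0.59 ± 0.12), and Hist1h1c fell with each (−1.78 ± 0.10 and −1.17 ± 0.10). Of mast cell and basophil genes Hdc, the histidine decarboxylase, rose by 4.58 ± 0.11 with HSV-1 and 5.40 ± 0.11 with SeV, and Gata2 rose by 0.61 ± 0.12 and fell (−0.35 ± 0.12). The eosinophil gene Siglecf fell with each (−0.79 ± 0.09 and −0.73 ± 0.09), and Ccr3 stood at −0.33 ± 0.19 and then fell (−0.71 ± 0.19). Car2, from the erythroid list, rose by 2.83 ± 0.20 with HSV-1 and stood at 0.39 ± 0.20 with SeV. Ighm, the only B cell gene tested of 7 in the data, fell (−1.57 ± 0.09 and −1.8 ± 0.09). Between genotype labels their changes ran from −0.24 (Gata2) to 0.31 (Hist1h1c, limma adjusted p = 0.51).

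Otud1 reads were not lower by label in mock or SeV, and no loss was detectable with HSV-1. A difference in scaling, which moves every gene alike, is argued against in mock: the log2 ratio of Otud1 by label lay 1.18 above the median of all other genes, and 10 of 12127 were at least as high. Exchanged genotype labels cannot be told apart from a knock-out that leaves transcripts: the libraries labelled WT held fewer Otud1 reads in mock and SeV, the direction an exchange predicts, but the ratio with HSV-1 was 0.95, the lowest of the 3 states, and no library lacked the reads. A knock-out that removes or changes part of the coding sequence while the transcript is still made may account for the reads; gene counts of a single-exon gene cannot show it, and read positions were not analysed here.

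Genes that differ between the genotype labels, 5 in limma, form the next pattern. Among 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one, and the highest other gave 0. The splits are too few for a share under 0.05. Several others put both libraries of an infection state on the same side. With infection as a covariate that state then adds nothing to the contrast, so their 0 calls say little. Variants carried along with the targeted locus may act on genes near it. Such local action is argued against, by position alone, for the 5, of which 0 lie on chromosome 2. The same holds for 120 of the 128 genes called by edgeR apart from Otud1, which lie beyond 20 Mb of it. Local action remains possible for the other 8, which lay within 20 Mb of Otud1 against 2.73 expected and an upper limit of 6. Among these (log2 change in edgeR) were Mrc1 (0.35), Plxdc2 (0.39), Fcna (1.20) and Ptges (−0.54), named after their values were seen. Action of such variants on distant genes, and variants elsewhere in the genome, were not tested. Cd4 and Gdf3 both lie on chromosome 6. A different mix of macrophage states cannot be told apart from an effect of the genotype itself, which stays open: the macrophage marker list (2 of its members, Mrc1 and Cd163, are also on the list of alternative activation) lay at or above percentile 98.4 of random lists in all 3 states, but the interval of its median held 0 in each (medians 0.13, 0.06 and 0.10), with 5, 6 and 6 of 15 members below 0.

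Stromal transcripts stood near 0 in both HSV-1 libraries, where 47 genes, 10 of them collagens, were lower with HSV-1 alone (limits of −2.5 and −0.7, chosen after the data were seen to describe the pattern), against 3 with SeV alone. Scaling is argued against by size alone, since total-count scaling shifted the median of all genes by only −0.59 on the log2 scale. The 7 markers that fell were a median of at least 242.9-fold lower (floor of 3 reads over the 2 libraries) under each of 3 scalings. They were picked because they fell, and so small a shift could not undo such a fold, so the 3 scalings are no separate test. Stromal cells absent from, or lost in, the HSV-1 cultures cannot be told apart from an effect of the virus on these transcripts. All 11 stromal and endothelial markers tested kept a median of 1.43% of mock, but 7 fell and 4 rose (Pdgfrb, Kdr, Cdh5 and Pecam1, which stood at 501.2% of mock). Cdh5 and Pecam1 had only 42 and 21 reads over both mock libraries, against 484 for Pdgfrb and 1074 for Kdr, and Kdr also rose with SeV. The rises of Cdh5, Pecam1 and Kdr therefore do not show that stromal cells remained. Pdgfrb went from 484 to 1488 reads (498% of mock), and the cells it came from were not examined, so its rise leaves the question open. Col3a1 and Dcn went from 1206 and 520 mock reads to 0. Transcript decay alone would need a median half-life of at most 0.757 h over the 7 under each of 3 scalings, and a biological effect of the virus on these cells or their RNA was not tested.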
